A study of Mus musculus with 2 samples.

How the data were processed

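Kidney tissue of female mice of strain B6CASTF1/J aged 36 days was profiled by DNase-seq. Per the labels there were 2 libraries, biological replicates 1 and 2 of 1 group, and no control or second condition. The labels number the females separately but carry the same donor entry for both samples, so that independence of the animals rests on the replicate numbers.

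Per the deposited description, the authors derived each file from a filtered alignment to mm10, separately for each library. The aligner, the peak caller and their versions are not given in the sources used here, nor are read totals. The authors' peak files hold a signal value per peak, the peak height, which in each library was a whole multiple (within 0.02) of 1 step, so the authors had scaled it by 1 factor per library. The scale is not stated, and heights were used to describe, rank or filter peaks and, as log2 ratios over shared peaks, to compare the libraries. The deposited FDR files hold a false discovery rate per interval, all below 0.05. The deposited footprint files hold intervals with the value 0.01 in every row, taken as the threshold of the set, so footprints had no score of their own. Of the 2 peak sets of each library, every peak of the stricter one held a position at a false discovery rate of at most 0.001 and every peak of the wider one a position at a rate of at most 0.05, as checked against the FDR files. The stricter set was used throughout, and the wider one as an alternative.

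Genes came from GENCODE release M21 on the mm10 sequence, with 21 chromosomes. A gene had a promoter peak when a peak overlapped the 1 kb on either side of the start site of any of its annotated transcripts. Peaks were assigned by their middle to promoter, exon, intron or intergenic sequence, in that order. Peaks of replicate 1 and replicate 2 were called shared when they overlapped by at least 1 base. Shares were compared with 100 random placements of the peaks, each anywhere on its own chromosome, unassembled bases included. Footprints were matched when they overlapped over at least 50% of the shorter. Consensus sequences of 24 motifs were searched on both strands in shared regions, and the share of matches wholly inside a footprint was divided by that of 20 column shuffles of the consensus.

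The gene lists comprised 26 written by hand, with 366 symbols, and 2 families chosen by symbol. Hand-written lists covered proximal tubule, thick ascending limb, distal convoluted and connecting tubule, principal cells, intercalated cells, podocytes, endothelium, stroma and mural cells, immune cells, erythroid cells, adipocytes, adrenal cortex, hepatocytes, striated muscle, neurons, male germ cells, nephron progenitors, kidney transcription factors, transcription factors of other organs, housekeeping genes, genes biased to male or to female kidney, and 4 groups of Hox genes. The families were olfactory and vomeronasal receptors. Each list was tested by Fisher's exact test against all other protein-coding genes, against 10000 random lists matched on the decile of the observed over expected CpG ratio in 1001 bp around the start site, and, for the median number of shared peaks in the gene and 10 kb on each side, against 10000 random lists matched on the decile of gene length. All tests were two-sided, with Benjamini-Hochberg adjustment over the 28 lists and a threshold of 0.05. With 1 group there was no test between groups. The loss of promoter peaks in replicate 2, by list and over all hand-written lists, and the height ratio of shared peaks, were compared between each list and random lists, matched on height, by permutation. For the ratio, random lists that were not matched were also drawn.

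Named genes were chosen by a rule written before the data were examined. For each list it took up to 4 members with the highest mean rank of their strongest promoter peak over the libraries, and the members without a promoter peak in either library where they were 5 or fewer, or else the first 3 in list order. It also took the 10 highest shared peaks on the autosomes and X, the 10 genes with most shared peaks, the 5 highest unshared peaks of each library, any Hox gene, Xist and peaks on Y. Not every gene that the rule took is described or drawn. Members with a peak in 1 library alone, further members named to complete a small count, and the promoters with a footprinted motif were chosen after their values were seen.

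The alternatives were start-site windows of 500 and 2500 bp, the stronger 50% of peaks, the wider peak set, other overlap rules, flanks of 50 kb or none, peaks away from start sites, and each replicate left out. After the data had been seen, counting a peak only for its nearest start site and using only starts of protein-coding transcripts were added. Reads on the CAST/EiJ or C57BL/6J allele were not analysed here. The steps were tested on simulated data. The CpG-matched test called 3.5% of 200 unchanged lists of 15 genes and 100% of 100 planted lists. Every planted gene was given a promoter peak and came from the lowest CpG deciles. That result therefore says nothing of CpG-rich lists or of smaller differences. The length-matched test called 2% of 100 unchanged lists and 85% of 100 lists with counts more than doubled. A planted motif gave a ratio of 3.15 and one not planted 0.98. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and bedtools 2.31.1 merged the intervals of the FDR files and took the lowest rate within each peak. The random seed was 20.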

Results

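Chromatin accessibility was measured by DNase-seq, in which DNase I cuts nuclear DNA where it is not covered by nucleosomes and the cut ends are sequenced, in kidney tissue of 36-day-old female mice. The animals were of strain B6CASTF1/J, the first-generation hybrid of the laboratory strain C57BL/6J and the wild-derived strain CAST/EiJ. The labels name 2 libraries as biological replicates and number the females separately, so the design holds 1 group with n = 2 and no treatment or second tissue. Replicate 1 had 124504 peaks covering 22.7 Mb (0.834% of the genome) with a median width of 180 bp, and replicate 2 had 68056 peaks covering 12.8 Mb (0.468%) with a median width of 198 bp. The authors' footprints, short stretches protected from DNase I inside accessible regions, numbered 375848 in replicate 1 and 223827 in replicate 2, with a median width of 10 bp in both. Read totals are not given in the sources used here. The smallest steps between peak heights gave replicate 2 a relative depth of 0.911 against replicate 1, if a step is the worth of 1 cut. Peak heights are the authors' own signal values on a scale that is not stated, so the heights of single genes in replicate 1 and replicate 2 are given side by side without a test between them.

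Promoter peaks in both libraries were more frequent at genes of the proximal tubule, of the endothelium, of kidney transcription factors and of housekeeping functions than at all other genes. Of 21938 protein-coding genes, 13314 (60.7%) had a peak within 1 kb of an annotated start site in both libraries, 1359 in replicate 1 alone and 37 in replicate 2 alone, and 7228 in neither. In replicate 1 alone the share was 66.9%, against 20.5% with its peaks placed at random once. The share with a peak in both libraries was 8.98% in the lowest decile of promoter CpG content and 93.9% in the highest. Each of 28 gene lists, fixed before the data were examined, was therefore compared both with all other genes (Fisher's exact test) and with 10000 random lists matched on promoter CpG content. Both tests were two-sided with Benjamini-Hochberg adjustment over the lists. Matching used the CpG content at the gene's 5′ end and not the number of annotated start sites, which differs between genes. Genes are not replicates, so these p-values describe the 2 libraries and not other mice. Among the lists, 4 were above and 10 below all other genes at an adjusted p of 0.05, and 4 were above and 7 below their CpG-matched lists.

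Proximal tubule genes, which encode the transporters and enzymes that reclaim filtered solutes, had promoter peaks in both libraries in 21 of 24 cases, against 60.7% of other genes (Fisher's exact test, adjusted p = 0.0128) and a median of 45.8% in CpG-matched lists (adjusted permutation p = 0.000933). That permutation value is the smallest the random lists could give, 0.0002 before adjustment. The highest peaks of the list had heights of 15.2 in replicate 1 and 16.4 in replicate 2 at Slc6a19, a carrier of neutral amino acids, and of 9.76 and 8.14 at Pck1, an enzyme of gluconeogenesis. Ggt1, which breaks down glutathione at the brush border, had 8.58 and 7.01, and Lrp2, the endocytic receptor megalin, had 7.46 and 5.11. The Pck1 peak overlapped the gene's 5′ end, at 2:173152581-173153080 (mm10), and the Lrp2 peak spanned the gene's 5′ end at 2:69586021-69586260. Slc22a6 and Dpys had a promoter peak in replicate 1 alone, and Slc22a8, a carrier of organic anions, had none within 1 kb in either library. Counted over the gene and 10 kb on each side, proximal tubule genes had a median of 6 shared peaks, against 2.5 in lists matched on gene length (adjusted permutation p = 0.00187). Among the stronger 50% of each library's peaks the share with a promoter peak was 62.5% and no longer differed from all other genes (Fisher's exact test, adjusted p = 0.505), and the call on peaks around the genes was lost with flanks of 50 kb (adjusted p = 0.0795) and within the gene body alone (adjusted p = 0.0691).

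Markers of the distal nephron were a mixed group. In the thick ascending limb, the segment that reabsorbs salt without water, 8 of 11 genes had promoter peaks in both libraries, against a CpG-matched median of 45.5% (adjusted permutation p = 0.102). Without replicate 1 the share was 81.8% and passed the threshold (adjusted permutation p = 0.0196), and Cldn19 had a peak in replicate 2 alone. Heights in replicate 1 and replicate 2 were 9.65 and 5.55 at Egf, 5.39 and 4.38 at Umod, which encodes uromodulin, and 3.47 and 4.58 at the potassium channel gene Kcnj1. The tight junction genes Cldn14 and Cldn16 had no promoter peak in either library. In the distal convoluted and connecting tubule 7 of 10 genes had promoter peaks in both libraries (CpG-matched median 60%, adjusted permutation p = 0.618). Wnk1 and Wnk4, kinases that regulate salt transport, had heights of 15 and 12.5, and of 9.36 and 5.85, and the sodium chloride cotransporter gene Slc12a3 had 7.52 and 6.54. Trpv5 and Klhl3 had a peak in replicate 1 alone, and Pvalb, which encodes a calcium-binding protein, had none. In the wider of the authors' peak sets 100% of this list had promoter peaks and the list passed the threshold against all other genes (exact test, adjusted p = 0.0338) and CpG-matched lists (adjusted permutation p = 0.0127).

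In collecting duct principal cells, which take up water and sodium, 8 of 10 genes had promoter peaks in both libraries (CpG-matched median 50%, adjusted permutation p = 0.186). The sodium channel subunit gene Scnn1g had heights of 6.41 and 3.67 in replicate 1 and replicate 2, and the water channel genes Aqp4 and Aqp3 had 2.59 and 2.05, and 2.67 and 1.4. Gata3 had 1.29 and 4.28, the values coming from separate peaks about 1 kb apart. Avpr2, the vasopressin receptor gene, and Scnn1b had a peak in replicate 1 alone, and without replicate 2 the share of 100% passed the threshold (adjusted permutation p = 0.0241). The same share in the wider peak set gave an adjusted p of 0.0338 by the exact test and of 0.0127 by permutation. Intercalated cells, which move acid and base, had the lowest share of the nephron lists: 4 of 11 genes, equal to the CpG-matched median of 36.4%. Atp6v0a4, a proton pump subunit, was the exception within the list, with heights of 10.3 and 7.27 and 13 shared peaks in and around the gene. Atp6v1b1 had 2.25 and 1.47, Hmx2 0.742 and 0.856, and Atp6v0d2 0.547 and 0.815. Slc4a9, Slc26a4, Foxi1 and Insrr had a peak in replicate 1 alone, and Atp6v1g3, Slc4a1 and Aqp6 had none. Against all other genes the list was lower only among the stronger 50% of peaks (18.2%, exact test, adjusted p = 0.0481).

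**Figure D1:**
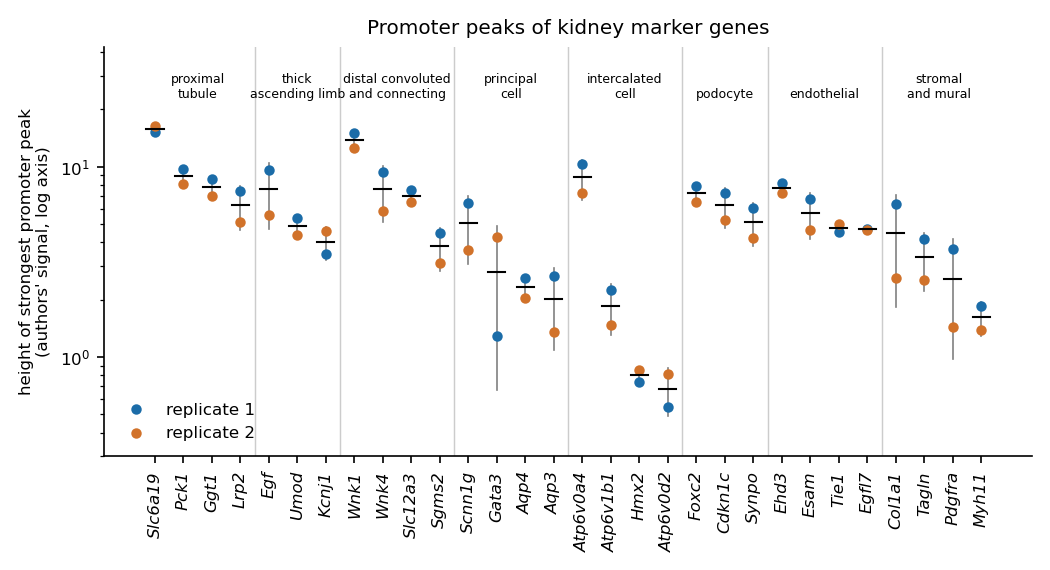
Height of the strongest promoter peak (the authors' signal, log axis) of up to 4 marker genes in each of 8 kidney cell type lists, with 1 point per library, a bar at the mean and lines of 1 SD (n = 2). Slc6a19 was the highest of these genes, at 15.2 and 16.4, and Gata3 and Pdgfra had the widest spread on this axis, their points, like those of Esam, coming from different peaks in replicate 1 and replicate 2.

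Endothelial genes had promoter peaks in both libraries in 16 of 17 cases (Fisher's exact test, adjusted p = 0.0116; CpG-matched median 52.9%, adjusted permutation p = 0.000933), and both calls held under every alternative tried. Heights in replicate 1 and replicate 2 were 8.25 and 7.23 at Ehd3, an endocytic trafficking gene marking glomerular endothelium, 6.80 and 4.62 at separate peaks of the junction gene Esam, 4.53 and 5.02 at the receptor kinase gene Tie1, and 4.71 and 4.66 at Egfl7. Tek had a peak in replicate 1 alone. The median endothelial gene had 8 shared peaks in and around it, against 3 in length-matched lists (adjusted permutation p = 0.0042), a call lost with flanks of 50 kb (adjusted p = 0.127) and within the gene body alone (adjusted p = 0.105). Podocytes, the filtering cells of the glomerulus, had 9 of 13 promoter peaks in both libraries, against a CpG-matched median of 76.9% (adjusted permutation p = 0.972). All 13 had a peak in replicate 1, so that without replicate 2 the list was above all other genes (exact test, adjusted p = 0.0161), and the genes missing from replicate 2 included Nphs1, Ptpro and Plce1. The transcription factor gene Foxc2 had heights of 7.95 and 6.54. The cyclin-dependent kinase inhibitor gene Cdkn1c had 7.31 and 5.22, and Synpo, which encodes an actin-associated protein, had 6.05 and 4.21 with 15 shared peaks in and around the gene. Stromal and mural genes had 8 of 15 (CpG-matched median 46.7%, adjusted permutation p = 0.85), with Col1a1 at 6.37 and 2.61, Tagln at 4.17 and 2.55, Pdgfra at 3.68 and 1.44 and Myh11 at 1.85 and 1.39. Dcn, Acta2, Notch3, Tbx18 and Foxd1 had a peak in replicate 1 alone, and Lum and the renin gene Ren1 had none. With a start-site window of 2500 bp Ren1 had a promoter peak in both libraries. This list passed the CpG-matched threshold without replicate 2 (86.7%, adjusted permutation p = 0.0236) and was below all other genes among the stronger 50% of peaks (13.3%, exact test, adjusted p = 0.00683).

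Transcription factor genes separated by organ. Of 33 factors of the kidney, 32 had promoter peaks in both libraries (Fisher's exact test, adjusted p = 2.09e-05; CpG-matched median 69.7%, adjusted permutation p = 0.000933), the exception being Foxi1, with a peak in replicate 1 alone. Heights were 23.6 and 19.7 at Nr3c2, the mineralocorticoid receptor gene, 13.2 and 13.6 at Elf3, 13.6 and 9.19 at Maf, and 12.6 and 9.62 at Ppara, a regulator of fatty acid oxidation. Of 23 factors of other organs, 3 had promoter peaks in both libraries (adjusted p = 2.34e-05; CpG-matched median 73.9%, adjusted permutation p = 0.000933), and both calls held under every alternative tried. They included Lhx3 at 5.47 and 2.53, and Atoh1, while the muscle factor gene Myod1 and the endocrine and neuronal factor genes Neurog3 and Neurod1 had none. In replicate 1, 6 of these 23 genes had a promoter peak. Among the stronger 50% of peaks the kidney factors were no longer above CpG-matched lists (78.8% against 60.6%, adjusted permutation p = 0.0756). They had a median of 5 shared peaks in and around the gene, against 3 in length-matched lists (adjusted permutation p = 0.0847), which passed the threshold without replicate 2 (10 against 5, adjusted permutation p = 0.0042). All 24 housekeeping genes had promoter peaks in both libraries (adjusted p = 4.3e-05; CpG-matched median 83.3%, adjusted permutation p = 0.0162, or 0.0921 without replicate 2), led by Rplp0 at 24.7 and 27.9, Rpl13a at 23.6 and 22.1, Ywhaz at 22.6 and 18.2, and Eef2 at 23.1 and 16.8. Their median of 4.5 shared peaks exceeded the 2 of length-matched lists (adjusted permutation p = 0.00933), though not within the gene body alone (adjusted p = 0.153) nor among peaks over 1 kb from every start site (adjusted p = 1).

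Genes of blood cells, liver and adrenal cortex had fewer promoter peaks than all other genes, and shares below their CpG-matched medians that did not pass the threshold. Immune genes had 2 of 16 in both libraries (Fisher's exact test, adjusted p = 0.000471; CpG-matched median 25%, adjusted permutation p = 0.408). These were Cd74, of antigen presentation, at 1.53 and 1.33, and the myeloid factor gene Spi1 at 1.27 and 0.886, while Ptprc, Cd68 and Csf1r had none. Erythroid genes had 1 of 10 (exact test, adjusted p = 0.00506; CpG-matched median 30%, matched p = 0.189), the erythropoietin receptor gene Epor at 1.6 and 1.04, with none at the globin genes Hbb-bt, Hbb-bs and Hba-a1. Hepatocyte genes had 3 of 16 (exact test, adjusted p = 0.00442; CpG-matched median 31.3%, matched p = 0.408), namely Apoh at 8.81 and 5.70, Fga at 2.69 and 1.21 and Apob at 2.10 and 1.12 (separate peaks), with none at Alb, Ttr and Serpina1a. The Apoh peak at 11:108343861-108344060 lay 33 bp from a start site of Prkca. Adrenal cortex genes had 1 of 9, Star at 1.71 and 1.79, with none at the steroid synthesis genes Cyp11a1, Cyp11b1 and Cyp11b2, but this call was lost without replicate 1 (exact test, adjusted p = 0.0104, or 0.0624 without it; CpG-matched median 22.2%, matched p = 0.618). Adipocyte genes had 5 of 10 (exact test, adjusted p = 0.635; matched p = 1), with Pparg at 4.52 and 2.49 and Lpl at 2.27 and 1.02 beside Adipoq, Lep, Cidec, Ucp1 and Retn without a peak. The adipocyte list was below all other genes only among the stronger 50% of peaks (10%, exact test, adjusted p = 0.0181). In replicate 1, 5 of the 16 immune and 3 of the 10 erythroid genes had a promoter peak. The matched values in this paragraph are adjusted permutation p-values.

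Striated muscle genes had 5 of 18 promoter peaks in both libraries (Fisher's exact test, adjusted p = 0.0128; CpG-matched median 44.4%, adjusted permutation p = 0.358). Mylpf, a myosin light chain gene, had heights of 16.8 and 17.8 at 7:127208821-127209300, a peak also within 1 kb of a start of Tbc1d10b, and Actn3, Casq1 and Ckm had 10.5 and 8.69, 5.49 and 3.25, and 4.97 and 2.90. The Actn3 peak lay 57 bp from a start site of Zdhhc24 and the Ckm peak 67 bp from one of Klc3, and Ckm had no peak near the start of a protein-coding transcript of its own. Acta1, Myh1 and Myh2 had none. Neuronal genes also had 5 of 18 (adjusted p = 0.0128; CpG-matched median 66.7%, adjusted permutation p = 0.0021), but 12 had a peak in replicate 1, and both calls were lost without replicate 2 (adjusted p = 1, and 0.857 by permutation). Snap25 had 2.12 and 1.05 and Rbfox3 2.17 and 0.876, and Slc32a1, Neurod6 and Stmn2 had none. Male germ cell genes had 4 of 16 (adjusted p = 0.0116; CpG-matched median 56.3%, adjusted permutation p = 0.0199), namely Zpbp at 6.59 and 3.66, Dazl at 5.47 and 3.07, Meiob and Sycp3, the Zpbp peak lying 73 bp from a start of Spata48 and 387 bp from one of Zpbp, with none at the protamine and transition protein genes Prm1, Prm2 and Tnp1. With a start-site window of 2500 bp the muscle, neuronal and germ cell lists no longer differed from all other genes (adjusted p = 0.0925, 0.242 and 0.08), nor did the neuronal and germ cell lists differ from CpG-matched lists (adjusted permutation p = 0.0921 and 0.208).

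Genes of the nephron progenitor list had 4 of 9 promoter peaks in both libraries and 8 of 9 in replicate 1 (Fisher's exact test, adjusted p = 0.491). Wnt11 had heights of 3.36 and 1.88, Osr1 had 1.5 and 0.693, and Meox1 and Cited1 also had peaks in both; Six2, Eya1, Wnt4 and Wnt9b had a peak in replicate 1 alone and Gdnf had none. The list was below its CpG-matched median of 88.9% (adjusted permutation p = 0.0162), a call that was lost without replicate 2 (adjusted permutation p = 1), in the wider peak set (0.723) and when a peak counted only for its nearest start site (0.108). Against all other genes it was lower only among the stronger 50% of peaks (11.1%, exact test, adjusted p = 0.0265). Of genes expressed more in male kidney, 2 of 9 had promoter peaks in both libraries of these females (adjusted p = 0.0629; CpG-matched median 33.3%, adjusted permutation p = 0.975). Those were the cytochrome genes Cyp4b1 at 6.69 and 3.41 and Cyp2e1 at 4.52 and 2.93. Slco1a1, Cyp4a12a and Slc7a13 had none, and Kap, Cyp2j13, Acsm3 and Cyp7b1 had a peak in replicate 1 alone. Of genes expressed more in female kidney, 2 of 5 had peaks in both (adjusted p = 0.543, exact test), Abcc3 at 2.96 and 2.35 and the prolactin receptor gene Prlr at 2.84 and 2.18, with Slc7a12 and Cyp4a14 in replicate 1 alone and none at Slc22a29.

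The Hox genes, which set position along the body axis, had promoter peaks in both libraries up to paralog 10 and, beyond it, at Hoxc13 alone. Both libraries had peaks at 7 of 12 genes of paralogs 1 to 4, 8 of 11 of paralogs 5 to 8, 5 of 10 of paralogs 9 to 11 and 1 of 6 of paralogs 12 to 13. The last group was below its CpG-matched median of 83.3% (adjusted permutation p = 0.0021), under every alternative tried, with Hoxc13 at 1.52 and 1.16 and no peak at Hoxa13, Hoxb13, Hoxc12, Hoxd12 or Hoxd13. Against all other genes its adjusted p was 0.0662 by Fisher's exact test, and 0.0346 without replicate 2, 0.0397 in the wider peak set and 0.0222 among the stronger 50% of peaks. Paralogs 1 to 4 and 5 to 8 had matched medians of 75% and 81.8% (adjusted permutation p = 0.618 and 0.85). Paralogs 9 to 11 had an adjusted permutation p of 0.0523 against a matched median of 90%, and of 0.0457 without replicate 1. Heights in replicate 1 and replicate 2 were 9.26 and 6.50 at Hoxb4, 11.9 and 7.85 at Hoxa7, 10.4 and 6.93 at Hoxa9, and 8.30 and 7.35 at Hoxd10. Hoxc10 had 13 and 7.44 at a peak on chromosome 15 (15:102966541-102966660), 195 bp from its start. The same peak was counted for Hoxc5, whose only start site near it is not that of a protein-coding transcript. The genes lie close together, and 1 peak can count for more than 1 of them: paralogs 1 to 4 had a median of 4.5 shared peaks and paralogs 5 to 8 of 6, against 1.5 and 1 in length-matched lists (adjusted permutation p = 0.0256 and 0.00448). Among peaks over 1 kb from every start site neither call held (adjusted permutation p = 0.0518 and 0.093), nor within the gene body alone (adjusted p = 1 for each), and with flanks of 50 kb the first was lost (adjusted p = 0.127). Paralogs 9 to 11 had 4 against 1 (adjusted permutation p = 0.0896, or 0.035 without replicate 1, 0.0218 without replicate 2 and 0.0105 among the stronger 50% of peaks).

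Receptor genes of the nose had almost no promoter peaks. Of 1135 olfactory receptor genes, 3 had promoter peaks in both libraries, Olfr433, Olfr54 and Olfr1375, against a CpG-matched median of 18.6% (adjusted permutation p = 0.000933). Of 331 vomeronasal receptor genes only Vmn1r4 had one, at 10.4 and 7.63, against 15.1% (adjusted permutation p = 0.000933). That peak at 6:56923861-56924120 also lies within 1 kb of a start site of Nt5c3, a nucleotidase gene. Olfactory receptor genes with a promoter peak in replicate 1 numbered 14 (1.23%). The median gene of either family had 0 shared peaks in and around it, against 2 in length-matched lists (adjusted permutation p = 0.00187 for each). Among peaks over 1 kb from every start site the medians were 0 for the families and for their matched lists alike, and no call remained.

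**Figure D2:**
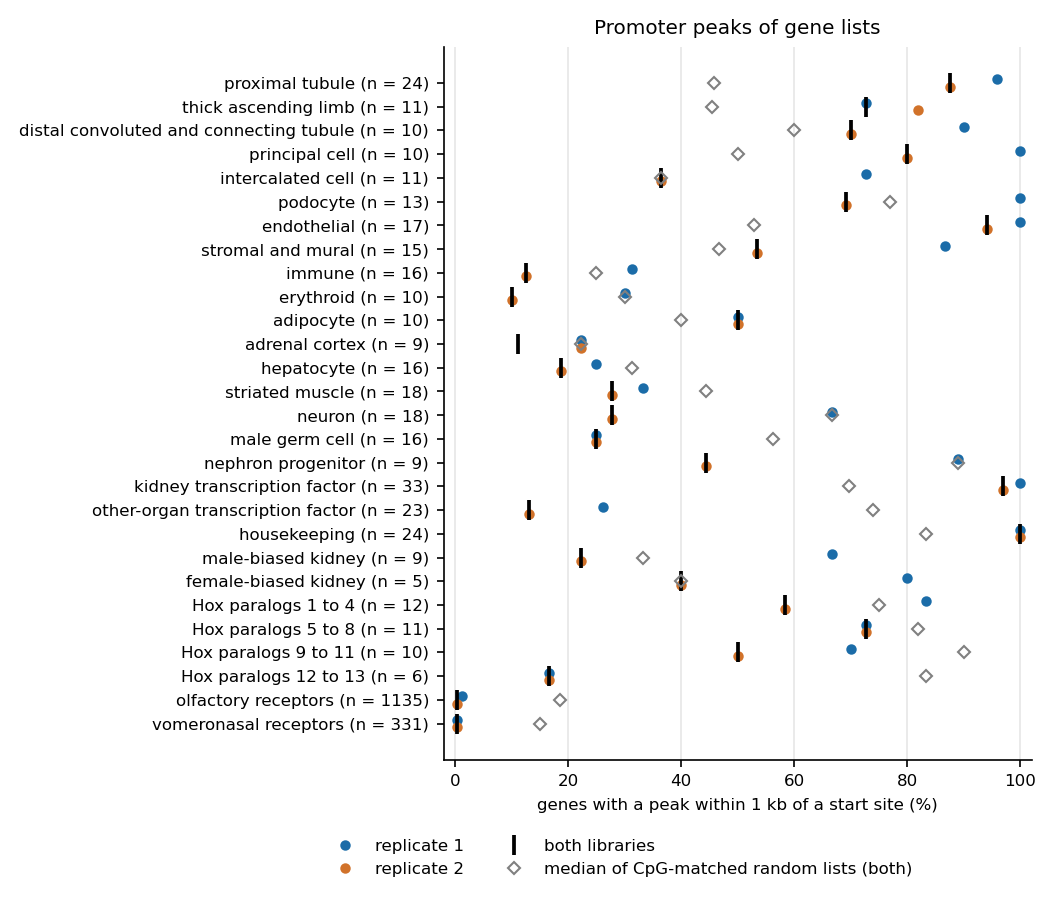
Percent of the genes of each of 28 lists with a peak within 1 kb of a start site, for replicate 1, replicate 2 and both libraries, with the median of 10000 CpG-matched random lists (for both libraries) as open diamonds. Housekeeping genes reached 100% and kidney transcription factors 97.0%, and olfactory receptors stood at 0.264%.

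The peak at Slc6a19 was not at the gene's 5′ end. Slc6a19 (ENSMUSG00000021565.16) occupies 13:73679745-73704865 on the minus strand, and its highest peak lay at 13:73692421-73692760 in replicate 1, with its middle in an exon and 12274 bp from the gene's 5′ end. The nearest annotated start was that of a transcript not classed as protein-coding, 45 bp from the middle of the peak, and the nearest protein-coding start was 8189 bp away. That start had a lower peak of its own, at 13:73700661-73700900 in replicate 1, with heights of 4.48 and 2.97. Within 55.1 kb around the gene replicate 1 had 14 peaks and replicate 2 had 12. Other marker genes also had their highest promoter peak near an internal start site, among them Egf, 30185 bp from the annotated 5′ end and 44 bp from a protein-coding start, and Slc12a3, 25040 bp and 2070 bp from these. Distances are from the middle of the peak of replicate 1. With the start sites of protein-coding transcripts alone, 13017 genes had a promoter peak in both libraries and every promoter call of the lists stayed on its side of the threshold. Of the genes named here only Ckm, Hoxc5 and Hoxc6 had fewer libraries with a promoter peak.

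**Figure D3:**
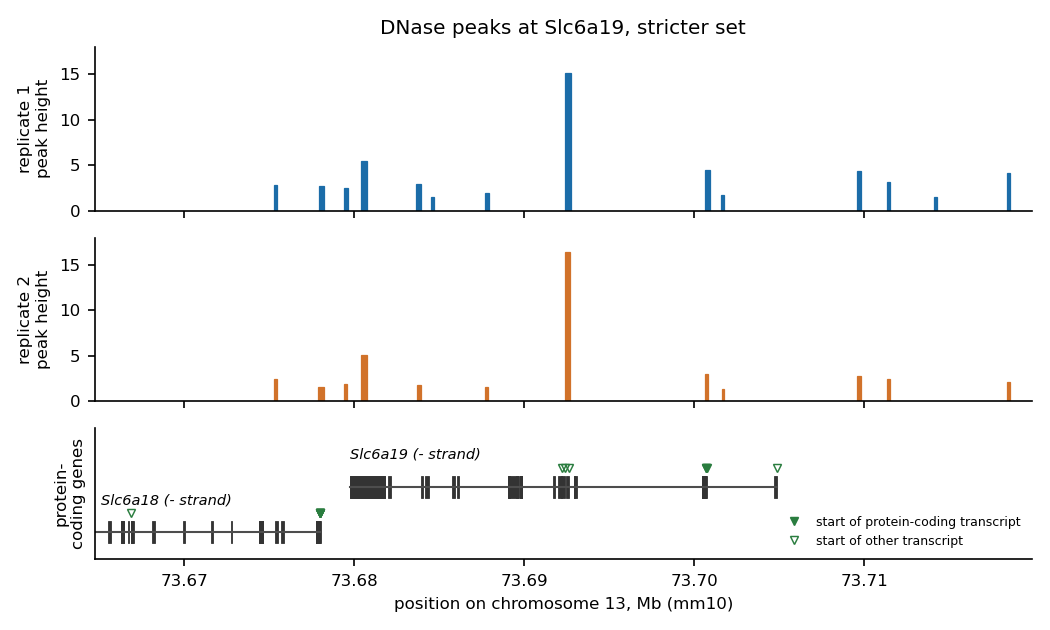
Peaks of the stricter set around Slc6a19 on chromosome 13 (mm10, position in Mb), drawn at the authors' peak height for replicate 1 and replicate 2 over the exons of Slc6a19 and Slc6a18, with filled triangles at the starts of protein-coding transcripts and open triangles at the starts of other transcripts. The tallest peak, 15.2 and 16.4, stands at internal starts of Slc6a19 and not at the gene's 5′ end.

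Some genes gathered many accessible sites, in raw counts that were not adjusted for gene length and so favour long genes. The gene models with most shared peaks in the body and 10 kb on each side were Gm20388 with 337, which spans 8:119910841-124345722 and overlaps many other genes, and Fgfr2 with 161, annotated over 7:130162451-133123350. The Fgfr2 span also takes in the promoter peak of Hmx2, so neither count belongs to a single gene. Pde4d had 57, Tns1 54, Syn3 52, Gse1 49, Prkce 48, Arhgap26 45, Camta1 42 and Rora 40. Across all protein-coding genes the median was 2, and 5332 genes had none.

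The tallest peaks shared by the libraries stood mostly at promoters. By mean rank of height over the libraries they were led by a site 21 bp from a start of Dynlt1b, a dynein light chain gene, at 17:6430001-6430180, with 66.5 in replicate 1 and 50.7 in replicate 2. Dnpep, an aspartyl aminopeptidase gene, had 52.7 and 48.8 at 1:75317581-75317940, Gm21887 had 66.8 and 44.1 at X:170009841-170010160, and the vesicle trafficking gene Rab11b had 51.1 and 48.4 at 17:33760381-33760640. Of the 10 highest, the rest within 1 kb of a start site belonged to Bahcc1, Ankhd1, Hexim2, Kdm6a and Hnrnpc. The exception was an intergenic site at X:143482981-143483140, 35530 bp from the nearest start, of Pak3, with 52.2 and 41.4. By position, 52.7% of the peaks of replicate 1 (65636) overlapped a peak of replicate 2, and 96.3% of the peaks of replicate 2 (65510) overlapped one of replicate 1, against medians of 1.0% and 1.84% in 100 random placements. Among equal numbers of the strongest peaks the shares were 81.4% and 81.3%, and of the 3402 highest peaks of each library 99.97% and 100% were found in the other. Over 64085 regions shared one to one, heights had Spearman's rho of 0.916 and Pearson's r of 0.935 on the log2 scale, across regions, which are not replicates. The median difference of replicate 2 from replicate 1 was −0.61 on the log2 scale (interquartile range −0.90 to −0.33), with 92.4% of regions lower in replicate 2.

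**Figure D4:**
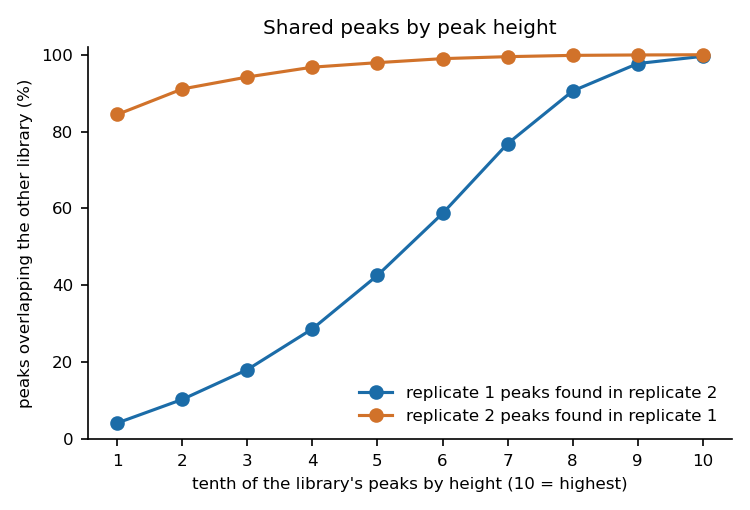
Percent of the peaks of each library that overlap a peak of the other by at least 1 base, by decile of the library's own peak heights. The share rose from 4.18% to 99.6% for replicate 1 and from 84.4% to 99.99% for replicate 2.

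Peaks found in a single library were low in the median, and the highest of them lay close to a peak of the other library. The highest of replicate 1 without overlap in replicate 2 were near Prrc2a (15.6, 17:35165301-35165500), Fahd1 (13.3), Limk1 (13.3), Ttc16 (12.5) and Leprot (12.4), each at a promoter and 20 to 120 bp from a peak of replicate 2. The highest of replicate 2 without overlap were near Crlf2 (6.41), Gtf2a1 (5.05), Smad2 (4.34), Ldhd (4.10) and S100a10 (4.0), 0 to 60 bp from a peak of replicate 1. All of these sites lay wholly inside the other library's regions at a false discovery rate of 0.05. Replicate 1 had 58868 unshared peaks with a median height of 0.752, against 2.52 for its shared peaks, and replicate 2 had 2546 with a median of 0.713, against 1.52. Of the unshared peaks 16% in replicate 1 and 29.8% in replicate 2 lay within 1 kb of a start site, beside 32.5% and 32.4% of the shared ones. The number for replicate 2 was 4027 when peaks overlapped over less than 50% of their width were counted.

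Promoters held many more peaks than their length would give. By midpoint, 24% of the peaks of replicate 1 and 31.7% of replicate 2 lay within 1 kb of a start site of a protein-coding gene (27.9% ± 5.40, SD, n = 2), against 3.90% and 3.96% in random placements, or 6.16 and 8.01 times more. Exons outside promoters held 3.74% and 3.55% (random 2.77% and 2.79%) and introns 35.8% and 31.7% (random 34.5% and 34.6%). Intergenic sequence held 36.4% and 33.1%, against 58.8% and 58.7% in random placements.

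Footprints covered consensus sequences of ubiquitous and of kidney-related factors. In the regions shared by the libraries, 82.1% of 803 matches to the CREB consensus lay wholly inside a footprint of replicate 1 and 63.4% inside one of replicate 2, 8.69 and 11.2 times the share of shuffled consensus sequences. NRF1, a regulator of nuclear genes for mitochondria, had ratios of 6.01 and 6.40 over 360 matches, and the insulator protein CTCF had 5.11 and 4.13 over 3093 matches, 94.4% of them inside a footprint of replicate 1 and 58.1% in replicate 2. Among factors known in kidney or liver, HNF4 had ratios of 4.42 and 4.21 over 1615 matches and HNF6/ONECUT 4.28 and 2.90 over 345. The estrogen-related receptor consensus had 2.64 and 1.54 over 428, and GRHL 1.61 and 1.27 over 110. ETS had 3.20 and 3.76, YY1 3.34 and 2.48, NFY 1.52 and 1.94, SP/KLF 1.43 and 1.57, AP-1 1.40 and 1.33, and TFAP2 1.18 and 1.22. FOX motifs lay inside footprints less often than their shuffles, at 0.372 and 0.235, as did the MyoD E-box at 0.392 and 0.551. TEAD had 0.875 and 0.599, and GATA 0.734 and 0.992. Some consensus sequences were rare: of 35 REST matches 31 lay inside a footprint of replicate 1 and 11 inside one of replicate 2, of 23 RFX matches 22 and 18, of 14 HNF1 matches 7 and 3, of 74 MEF2 matches 5 and 4, of 30 PAX2/PAX8 matches 1 and 0, and none of 35 PU.1 matches or of the 1 IRX match. By position, 51.3% of the footprints of replicate 1 in shared regions matched one of replicate 2 over at least 50% of the shorter footprint, and 64.4% of replicate 2 matched one of replicate 1, against 23.5% and 27.9% in random placements within those regions. With a match touching a footprint by 1 base the TEAD ratios turned above 1 (1.34 and 1.23), and several others moved toward 1. These were 3.15 and 3.72 for CREB, 2.15 and 2.39 for NRF1, 1.8 and 1.87 for CTCF, 2.42 and 2.65 for HNF4, 2.19 and 2.15 for HNF6/ONECUT, 2.05 and 1.69 for YY1, 0.558 and 0.576 for FOX, and 0.789 and 0.839 for the MyoD E-box. Among peaks over 1 kb from every start site FOX and TEAD stayed below 1 in both libraries, while the E-box had 0.711 and 1.12 and GATA 0.767 and 1.19. There CTCF had 7.46 and 6.53, the estrogen-related receptor consensus 4.58 and 2.38, YY1 2.29 and 1.14, ETS 2.03 and 2.65, and NFY 1.13 and 1.20.

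**Figure D5:**
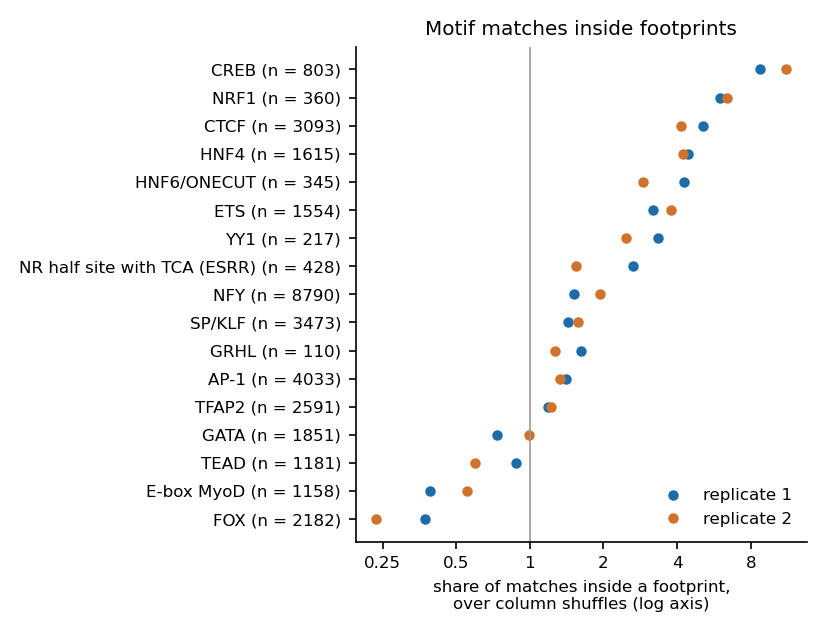
Share of the motif matches in shared regions that lie wholly inside a footprint, divided by that share for 20 column shuffles of the consensus (log axis, 1 marks no difference), for replicate 1 and replicate 2 and the 17 motifs with at least 100 matches. CREB, at 8.69 and 11.2, stands highest and FOX, at 0.372 and 0.235, lowest.

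Footprinted matches could be placed at single promoters of the listed genes. A CTCF match, GCCCTCTAGTGG, lay in a footprint of both libraries 714 bp upstream of Elf3 at 1:135259282-135259293 (mm10), within the sequence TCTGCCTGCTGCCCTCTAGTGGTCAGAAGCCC. The same 12 bases stood 916 bp from a start of Elf5 at 2:103445963-103445974. CTCF matches also lay 88 bp from a start of the podocyte gene Clic5, at 17:44188672-44188683 (GCCCCCTGCTGG), and inside the muscle gene Ckm, 777 bp from an annotated start, at 7:19405553-19405564 (CCACCAGATGGC). Ckm had no promoter peak at the start of a protein-coding transcript of its own, and its highest promoter peak lay nearest a start of Klc3. At the housekeeping gene Rplp0 a TFAP2 match, GCCAATAGGCA, lay 37 bp upstream of a start at 5:115559430-115559440. Over all shared regions TFAP2 matches lay inside footprints little more often than their shuffles (ratios of 1.18 in replicate 1 and 1.22 in replicate 2). Which factor left this footprint is therefore not known.

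The X chromosome had few peaks for its length and the Y chromosome almost none in these females. Xist, the RNA gene that silences an X chromosome in females (X:103460366-103483254), had peaks near its 5′ end in both libraries, with heights of 2.01 and 2.51 in replicate 1 and of 1.46 and 0.754 in replicate 2. The X carried 2787 peaks in replicate 1 and 1278 in replicate 2, or 0.326 and 0.271 of the median autosome per Mb. Chromosome 11 was the densest, at 1.44 and 1.56 times the median autosome. The Y carried 10 and 18 peaks, 0.00217 and 0.00707 of the median autosome per Mb. The tallest of the Y peaks lay near Gm21860, at 6.04 and 6.10. Of the Y peaks 9 of 10 in replicate 1 and 15 of 18 in replicate 2 shared at least 1 stretch of 31 bases with another chromosome.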

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

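Of the tests given here, those that counted a peak for its nearest start site alone or used only starts of protein-coding transcripts were chosen only after the data were seen. Of the list calls against all other genes, 3 of 4 higher and 6 of 10 lower ones held under every alternative tried, as did 2 of 4 and 4 of 7 against CpG-matched lists, and 0 of 5 and 0 of 2 for peaks around the genes. Peaks shared between libraries, 52.7% of replicate 1 and 96.3% of replicate 2, were 52.3% and 95.5% with at least 50% of the smaller peak overlapped, 46.8% and 85.6% with reciprocal overlap of 50%, 54.4% and 99.1% among the stronger 50% of peaks, 81.4% and 81.3% in equal numbers, and 54.1% and 93.0% in the wider set. Among the stronger 50% of shared peaks Spearman's rho was 0.887 and Pearson's r 0.933. With a start-site window of 500 bp exons held 4.42% and introns 36.9% of peaks, and with 2500 bp promoters held 35.3%, exons 2.66% and introns 29.0%, as the window's own size sets. The stronger 50% of peaks gave promoters 38.6%, exons 3.39%, introns 29.1% and intergenic sequence 28.9%, and the wider set gave exons 3.86%. Lists with more peaks around their genes numbered 2 with flanks of 50 kb, 0 within the gene body and 2 among peaks over 1 kb from every start site, where 0 were lower. Footprints matched by 1 base were 55.6% and 70.0%. The TEAD ratio turned to 1.29 with 1 base of overlap. Away from start sites 2 motif ratios above 0, those of FOX and TEAD, were below 1 in both libraries. PAX2/PAX8 and PU.1, with few matches, had ratios of 0 there in both. Replicate 2 had 4027 specific peaks when a peak overlapped over less than 50% of its width counted as specific. Except where a sentence names the window's size, the cause was not tested. Leaving out a replicate gave 13351 to 14673 genes with a promoter peak, 4 to 5 lists above and 9 to 10 below all other genes, and 5 to 8 lists below CpG-matched lists. Over 224 alternatives for single lists against all other genes, 10 brought a list past the threshold and 6 ended a call. Against CpG-matched lists these were 6 and 8 of 224, and for peaks around the genes 4 and 13 of 168. For named genes the number of libraries with a promoter peak stayed on its side in 824 of 880 alternatives, and 13 rose and 43 fell. Of single motif ratios, 4 lay within the spread between replicates with 1 base of overlap, 13 moved further and 1 changed sides, and away from start sites 7 lay within it and 10 moved. Without a replicate a motif ratio is that of the other library, which tests nothing. Sharing and height agreement need both libraries, so no replicate was left out there. The planned stricter threshold on footprints was not run, since every footprint carries the same value. Read depth is not given, so what depth limits was not measured.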

Other observations

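The tests of 26 gene families, of sequencing depth, of locations under the calling threshold, of promoters lost over all lists together and of height ratios by list were chosen only after the result was seen. The families were tested as one set (two-sided permutation tests against CpG-matched lists, Benjamini-Hochberg adjusted). Glutathione transferases, enzymes of detoxification, had promoter peaks in both libraries at 17 of 20 genes, against a matched median of 45% (adjusted permutation p = 0.00065), with heights of 24.8 in replicate 1 and 18.9 in replicate 2 at Gstm7 and of 18.9 and 16.4 at Gstm1, and none at Gstm3, Gstt4 and Gstp3. Subunits of the V-ATPase, the proton pump, had 21 of 23 (matched median 60.9%, adjusted permutation p = 0.00173), led by Atp6v0d1 at 30.8 and 22.9 and Atp6v1d at 21.9 and 18.3. Solute carriers outside the Slc22 family had 264 of 346 (65.9%, adjusted permutation p = 0.00065), and a median of 4 shared peaks against 3 in length-matched lists (adjusted permutation p = 0.00173). Complex I subunits had 36 of 37 (adjusted permutation p = 0.0238), cytosolic ribosomal proteins 73 of 76 (0.00563), mitochondrial ribosomal proteins 75 of 75 (0.00065), proteasome subunits 37 of 39 (0.0148) and Zfp zinc finger genes 334 of 394 (0.00065), all above their matched lists. The value 0.00065 is the smallest these permutations could give.

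Families below their matched lists included keratins with 6 of 49 (matched median 44.9%, adjusted permutation p = 0.00065), although Krt10, at 11.2 and 8.10, and Krt8, at 3.50 and 2.74, had peaks in both libraries. Potassium channels had 35 of 94 (0.00065), with the tubular channel gene Kcnj16 at 8.41 and 6.18. Protocadherins had 11 of 69 (0.00065), Wnt ligands 5 of 19 (0.00065), fibroblast growth factors 7 of 22 (0.00312), T-box factors 3 of 13 (0.00331), Sox factors 12 of 19 (0.0385) and taste receptors 2 of 38 (0.0406). The T-box genes were Tbx2, at 14 and 11.3, Tbx3 and Tbx6. Cytochromes P450 did not differ past the threshold in promoter peaks, with 35 of 99 above a matched median of 27.3% (0.0777), but had fewer shared peaks around the gene than length-matched lists, 1 against 2 (0.0065). Aquaporins (7 of 11), claudins (12 of 23), Slc22 transporters (11 of 25), UDP-glucuronosyltransferases (4 of 19), collagens (23 of 44), ABC transporters (34 of 50), interleukins (10 of 33), chemokines (8 of 31) and beta-defensins (5 of 42) did not pass the threshold. Values in parentheses are adjusted permutation p-values.

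Replicate 2 had fewer peaks than replicate 1, and lower heights at peaks shared one to one, although the median height over all its peaks was higher (1.46 against 1.33). If heights are proportional to cuts, fewer cuts alone would change every peak by 1 factor, whatever the scale of each library. The median log2 height ratio was −0.306 in the first decile of shared peaks, −0.745 in the fifth, the lowest of all, and −0.419 in the highest. The highest decile exceeded the fifth by 0.33 (95% interval over chromosomes 0.31 to 0.35). Shared peaks had to be called in both libraries, so low ratios can be missing among low peaks. If heights are proportional to cuts, the rise from the fifth decile to the highest argues against depth as the whole cause. If a step is also the worth of 1 cut, heights are already scaled for the relative depth of 0.911. Depth alone would then leave shared peaks about equally high in both libraries. Their median log2 ratio was −0.607 (interquartile range −0.901 to −0.333), which under that assumption argues against depth as the main cause of the lower heights. Unshared peaks of replicate 1 touched regions of replicate 2 at a false discovery rate of 0.05 at 25.9 times the random rate (47.2% against 1.82%). These regions also hold the called peaks of replicate 2, and 31086 of the 58868 unshared peaks touched none of them. Some locations may have fallen under the calling threshold in replicate 2, but these values cannot tell how many. A difference in recovery of GC-rich sequence cannot be told apart: the share found in replicate 2 was 7.96 percentage points higher on average for GC-rich than for GC-poor peaks, but deciles of height ranged from −0.771 to 16.1, since nearly all high peaks were found and the mean is held down by them. No biological explanation was tested, and a difference between the animals stays open.

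Promoters of marker genes with a peak in replicate 1 alone, such as Nphs1 and Slc26a4, could reflect low peaks lost at the rate of equally low promoters. Over all hand-written lists, 53 of 244 promoters were lost, within the central 95% of sets matched on height in replicate 1 (39 to 56). Of single lists 0 of 25 lost more at an adjusted permutation p under 0.05, a weak test for many of them. At a stricter cut, 0.05 divided by the number of lists, 22 could have passed. The losses needed ranged widely, such as 2 of 24 promoters for housekeeping genes and 8 of 8 for intercalated cells. Hox paralogs 9 to 11 lost 2 against a median of 0 (permutation p = 0.0068, adjusted 0.17). Another make-up of cell types in replicate 2 cannot be told apart: 2 of 8 kidney lists lay more than 1 promoter from the median of their matched lists, and the lowest adjusted permutation p was 0.868. Over shared peaks in and around the genes, the centred log2 height ratio of replicate 2 to replicate 1 was 0.27 for endothelial and 0.27 for thick ascending limb genes (adjusted permutation p = 0.0054 for each against height-matched lists). Among 27 lists, 7 passed an adjusted permutation p of 0.05 (9 against lists not matched on height). Kidney transcription factors (0.14) and adrenal cortex genes (0.68) were also above. The adrenal cortex value rests on only 3 genes, with at most 1 shared peak each. Male germ cell genes (−0.31), other-organ factors (−0.31) and olfactory receptors (−0.20) were below. The cause stays open.

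Promoter peaks at genes of the adrenal cortex, hepatocyte, striated muscle, neuron, male germ cell and other-organ factor lists were weighed against neighbouring genes and CpG content. Of 21 such genes, 1 (4.76%) lost its call when a peak counted only for the nearest start site. This argues against neighbouring start sites as the main source of the calls. A gene kept its call through any peak nearest a start of its own, however low. The count therefore cannot tell to which gene the highest peaks belong, and those of Apoh, Ckm, Actn3 and Zpbp lay nearest the start of another gene. Promoters rich in CpG that are open in most tissues might account for the promoter peaks at these genes: the median CpG ratio was higher by 0.205 in genes with a peak than in genes without one (98 genes), but with a permutation p of 0.0723 this cannot be told apart from chance. No biological explanation was tested.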
